A study of Rattus norvegicus with 12 samples.

How the data were processed

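Gene expression was measured in mucosal scrapes of the duodenum and the jejunum of Belgrade rats. The Belgrade rat carries a recessive mutation in Slc11a2, the gene of the divalent metal transporter DMT1, and homozygous (b/b) animals are known to be anaemic, while heterozygotes (+/b) served as the comparison. Per the labels' protocols, RNA was extracted with Trizol and a column kit, labelled with biotin and hybridised by the standard Affymetrix procedure. The series design describes 3 groups of rats per genotype, each of which supplied both tissues and was hybridised to 1 array per tissue, so there were 12 arrays in 4 groups of 3. The replicate is therefore a group of rats, and p-values of the genotype comparisons measure the spread between such groups. The main fits treated all 12 arrays as independent. P-values that compare the tissues, or the genotype effects between them, therefore leave out the pairing by group of rats. Only the fits with the rat group as a block take that pairing in.

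The deposited values were signal intensities per probe set on a linear scale, and MAS5 is named in the submitters' processing notes for 10 of the 12 arrays. The software version and background settings are not given in the sources used here. From the values, 10 arrays had a 2% trimmed mean of 500.2, whereas +/b duodenum replicates 2 and 3 had trimmed means of 51.6 and 126.6, as if the final scaling had been left out. Every array was therefore scaled to a trimmed mean of 500, which multiplied those 2 arrays by 9.69 and 3.95. Multiplication leaves the order of the probe sets within an array in place, but the noise of dim probe sets is multiplied with them.

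The file held 31099 probe sets, of which 57 were hybridisation and labelling controls and were removed from the tests. The platform annotation gave 1 gene for 20832 probe sets, several genes for 436 and none for 9831. Gene IDs of 20764 probe sets were found in the RefSeq gene table, and 0 symbols differed from the current ones. No gene was named from a probe set with several genes. For this reason no value is given for Fth1, 1 of the 10 genes of the advance list. Probe sets with a mean scaled signal of at least 100 over the 12 arrays were tested, which left 17694 probe sets, 13501 of them with 1 gene (10067 genes).

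Tests used log2(scaled signal + 16), so that changes of dim genes are understated. A linear model with 4 group means over all 12 arrays was fitted with limma 3.58.1 (R 4.3.3) with eBayes and an intensity trend. The p-values, two-sided, were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts were b/b against +/b in each segment, jejunum against duodenum in each genotype, and the difference of the genotype effects between the segments (the interaction, jejunum minus duodenum). Fold changes are given on the log2 scale with the standard error (SE) of the fit. Signals are means ± SD over 3 arrays.

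A set of 40 gene lists was drawn up before the data were examined, and 39 had the minimum of 3 measured genes. Of 1033 list symbols, 875 matched a probe set. Each gene was represented by the probe set of highest mean. Lists were tested with camera (limma) at a preset correlation of 0.01, again with an estimated correlation per list, and with fry. Genes named in the text were chosen by a rule fixed in advance. It took up to 10 called genes of largest change in each direction whose groups of 3 arrays did not overlap, 10 genes of iron handling and related pathways whatever their result, and up to 4 members of each list discussed. Other genes and probe sets named were chosen after their values were seen.

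The pairing of arrays by replicate number was checked by correlating deviations from the group means. Same-numbered duodenum and jejunum arrays of 1 genotype come from the same group of rats according to the series design. Their correlations lay between 0.19 and 0.28 in +/b and between 0.16 and 0.38 in b/b rats. Same-numbered jejunum arrays of both genotypes also deviated together (0.12 to 0.42), as did +/b jejunum with b/b duodenum arrays (0.14 to 0.45). Correlations of +/b duodenum with b/b duodenum (-0.06 to 0.16) and b/b jejunum arrays (0.03 to 0.26) were lower. Arrays of different genotypes came from different rats, so the correlations within a genotype do not single out a shared group of rats.

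The fits were tested on simulated data. With a seeded set of probe sets changed by known amounts, the duodenum contrast recovered 26.5% of changes of 1 on the log2 scale, 81.8% of changes of 2 and 100% of changes of 4, with 7 false calls among 145. The interaction contrast recovered 10.3%, 60.6% and 87.9%. The simulated noise was independent between arrays, and 68, 66 and 66 probe sets were changed by 1, 2 and 4. More true changes loosen the adjusted threshold, and the real duodenum contrast called only 7 probe sets. The simulated shares can therefore exceed what the real contrasts recover. Alternatives covered the pseudocount, the filter, the scaling, the variance model, array weights, replicate blocks, the list test and leaving out each array in turn. The number of arrays limits the precision, and an exact permutation test of 3 arrays against 3 cannot give p below 0.1. The highest Spearman correlation between 2 arrays was 0.945.

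For the explanations weighed in the closing section, predictions were written down before each result was seen, except that for blood RNA as a source of the Slc11a2, Cybrd1 and Tfrc differences, which was written after. The standard error of 1 of these tests, on Alox15 and the erythroid genes, was recomputed from the residual spread of the 12 arrays after the first version, taken from the intensity trend outside its range, was found to be wrong. A test on Slc11a2, Cybrd1 and Tfrc was also run in other forms after its first value was seen, beside the blood markers, as added signal and with the mean of all probe sets of a gene. The last form gave -3.47 standard errors for Slc11a2, -6.50 for Cybrd1 and -2.33 for Tfrc. Figures were drawn with matplotlib 3.10.9.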

Results

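The series asked how the small intestine of Belgrade rats differs between homozygotes (b/b) and heterozygotes (+/b) in the duodenum, where most dietary iron is taken up, and in the jejunum. Each of the 4 groups held 3 arrays. After scaling, the median signal per array lay between 108.5 and 181.5. The array of b/b duodenum replicate 1 stood apart from the others, with a median Spearman correlation of 0.836 to the other 11 arrays. The Belgrade allele is known as an amino acid substitution that leaves the Slc11a2 transcript in place, so its level does not check the genotype labels.

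In the duodenum, transcripts of apical iron uptake were higher in b/b than in +/b rats. Cybrd1, a brush border ferric reductase, rose 16.6-fold (log2 change 4.05 ± 0.41 SE, n = 3 per group), from a signal of 843 ± 286 to 16000 ± 8960 (limma, Benjamini-Hochberg adjusted p = 0.00112). Slc11a2, the metal transporter mutated in this strain, rose by 2.81 ± 0.38 on the dimmer of its 2 probe sets (limma adjusted p = 0.0107), from 836 ± 289 to 6150 ± 2450. Alox15, a 12/15-lipoxygenase, rose by 4.52 ± 0.36, from 14.5 ± 4.9 to 687 ± 119 (limma adjusted p = 9.88e-05). Hbb, a beta globin gene, rose by 2.43 ± 0.26, from 2720 ± 806 to 14300 ± 2390 (limma adjusted p = 0.00121).

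These 4 genes belonged to 7 probe sets past the threshold of 17694, all 7 of them higher in b/b and with no overlap between the groups of 3 arrays, which 8.7% of all probe sets showed against 10% by chance. The other 3 were a pair annotated to several genes (2.45 ± 0.28 and 2.68 ± 0.37) and 1 with no gene in the annotation (3.88 ± 0.48). At an unadjusted p under 0.05 there were 1092 probe sets, 443 higher and 649 lower, against 885 expected by chance. The +/b signal of Alox15 lay near the detection floor, and its change was 5.51 with a pseudocount of 1 and 3.25 with 64. The Slc11a2 call was lost without +/b replicate 1 or 2 or b/b replicate 2 or 3 (limma adjusted p from 0.0709 to 0.113), and without both arrays that had been deposited unscaled, which left 1 +/b array assumed to vary like the other groups, 3 probe sets were called, Slc11a2 (3.24, adjusted p = 0.0926) and Hbb (2.11, adjusted p = 0.0555) no longer among them.

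**Figure D1:**
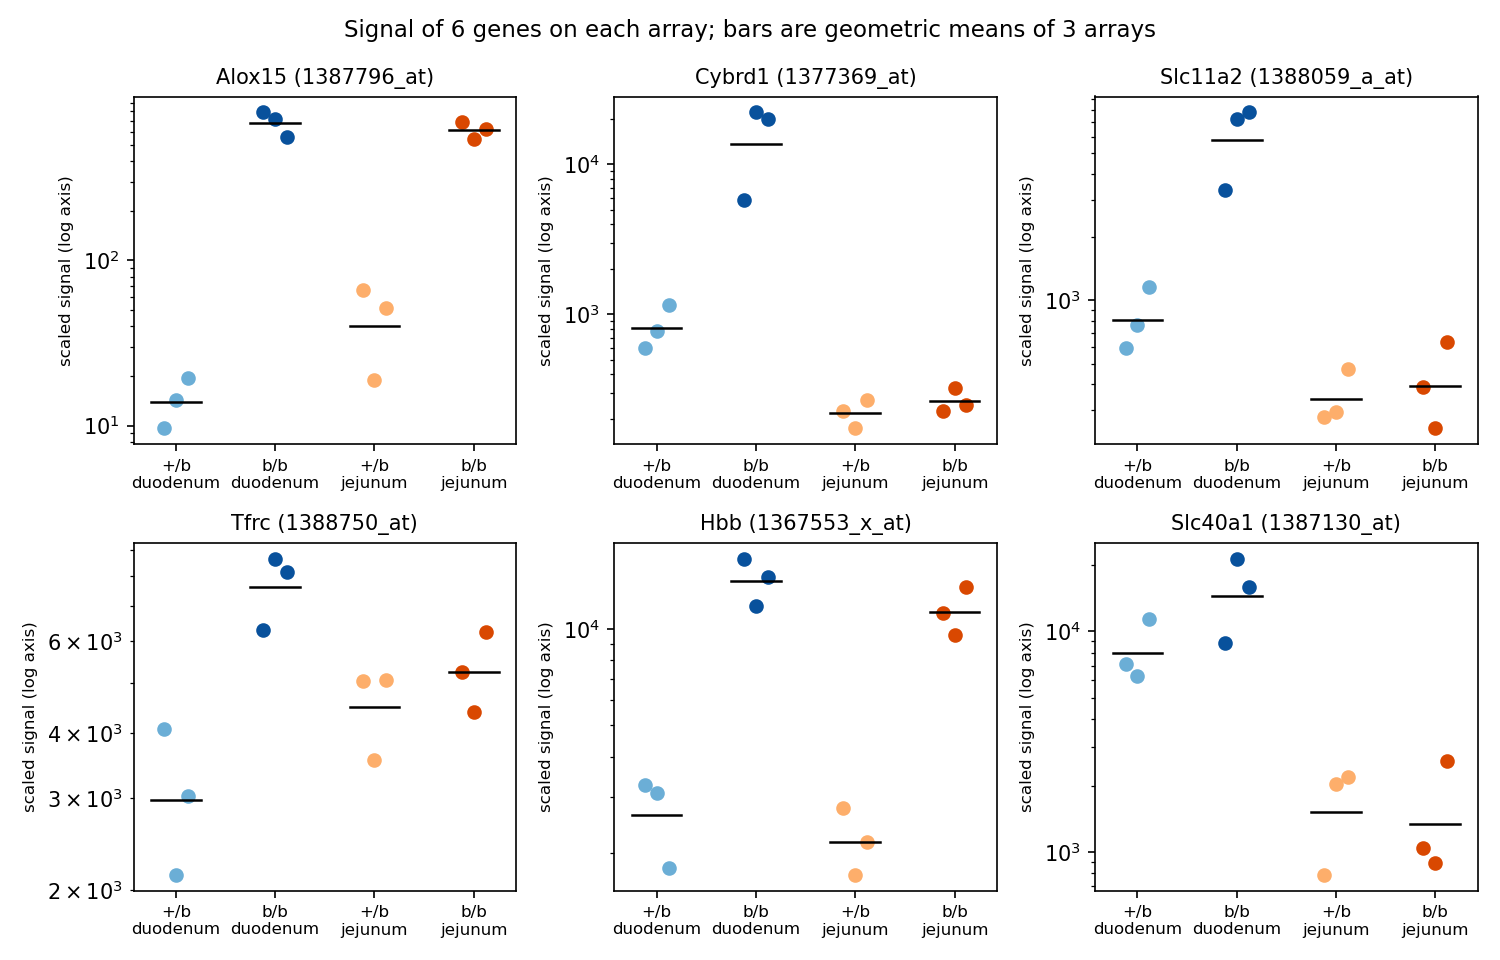
Scaled signal (log axis) of 6 genes on each of the 12 arrays, in 4 groups of 3, with points for arrays and bars for geometric means. Cybrd1 and Slc11a2 stand higher in b/b duodenum than in the other groups, while Alox15 and Hbb stand higher in b/b in both segments.

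Of the other genes fixed in advance, none passed the threshold in the duodenum. Slc11a2 on its brighter probe set had a change of 2.63 ± 0.55 (limma adjusted p = 0.312), from 4330 ± 1570 to 25900 ± 3680. Tfrc, the transferrin receptor, had a change of 1.35 ± 0.25 (limma adjusted p = 0.134) with no overlap between the groups. Its dimmer probe set had 1.21 ± 0.40 (limma adjusted p = 0.748), also without overlap. Slc40a1, the basolateral iron exporter, had 0.86 ± 0.46, and Atp7a, a copper exporter, 1.14 ± 0.46, each with overlapping groups on the brightest probe set of the gene, while a dimmer Atp7a probe set had 1.59 ± 0.62 without overlap (limma adjusted p = 0.789). Hmox1, a heme oxygenase, had 0.68 ± 0.53, the ferroxidase Heph 0.07 ± 0.19 and the metallothionein Mt1 0.34 ± 0.81 (limma adjusted p between 0.789 and 0.972 for these 5 genes).

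Among the gene lists, markers of blood and reticulocytes were higher in b/b duodenum, with a median change of 0.50 over 11 genes (camera in limma, adjusted p = 2.05e-07, and adjusted p = 0.0109 with an estimated correlation). Of these genes 1 was called over all probe sets and 2 when adjusted over the list alone, Hbb and the erythroid heme synthesis enzyme Alas2 (2.35 ± 0.41). The iron list of 24 genes was also higher (median 0.07, mean 0.51, camera adjusted p = 0.0164 in limma, and adjusted p = 0.142 with an estimated correlation). Its members Cybrd1, Tfrc and Slc11a2 passed when adjusted over the list alone, against 1 over all probe sets, and the list call was lost without +/b or b/b replicate 2 (limma adjusted p up to 0.107). Targets of the hypoxia-inducible factors had a median of 0.22 over 32 genes (limma camera adjusted p = 9.74e-06, and adjusted p = 0.0577 with an estimated correlation). Their smallest p-values belonged to the prolyl hydroxylase Egln3 (1.00 ± 0.28) and Ankrd37 (1.11 ± 0.33), and 0 members passed over all probe sets or when adjusted over the list alone.

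Cell cycle genes were lower in b/b duodenum at the preset correlation, with a median of -0.39 over 39 genes, 35 of them below 0 (limma camera adjusted p = 9.74e-06, and adjusted p = 0.811 with an estimated correlation). Of these, 0 were called over all probe sets and 1 when adjusted over the list alone, the kinetochore gene Cenpf (-1.19 ± 0.29), and the call was lost without +/b replicate 1 (-0.18, limma adjusted p = 0.0515). Crypt stem and progenitor markers had a median of -0.72 over 8 genes (limma camera adjusted p = 0.00179, and adjusted p = 0.478 with an estimated correlation). Ascl2 (-1.64 ± 0.42), a stem cell transcription factor, and Slc12a2 (-1.04 ± 0.28) passed when adjusted over the list alone, and 0 over all probe sets, and the call was lost without +/b replicate 1 or b/b replicate 2 (limma adjusted p up to 0.0547). The remaining calls were cholesterol synthesis (median 0.36, limma adjusted p = 0.86 with an estimated correlation) and fatty acid oxidation (median -0.17, limma adjusted p = 0.811 with an estimated correlation). Adjusted over the list alone, 0 members of the first and 1 of the second, Eci1 (-1.01 ± 0.25), passed, and 0 of either over all probe sets. Both calls were lost without +/b replicate 2 or b/b replicate 3, and the first also without b/b replicate 2 (limma adjusted p up to 0.708 and 0.408), its median running from -0.02 without b/b replicate 3 to 0.76 without b/b replicate 1. In all, 11 lists were called without +/b replicate 3, 12 without b/b replicate 1 and 4 without b/b replicate 2. Exocrine pancreas markers, which were not called here (median -0.99), averaged 13.56 on the log2 scale in +/b duodenum replicate 2 and 9.56 in b/b duodenum replicate 3, against 6.51 to 7.34 in the other 4 duodenum arrays.

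**Figure D2:**
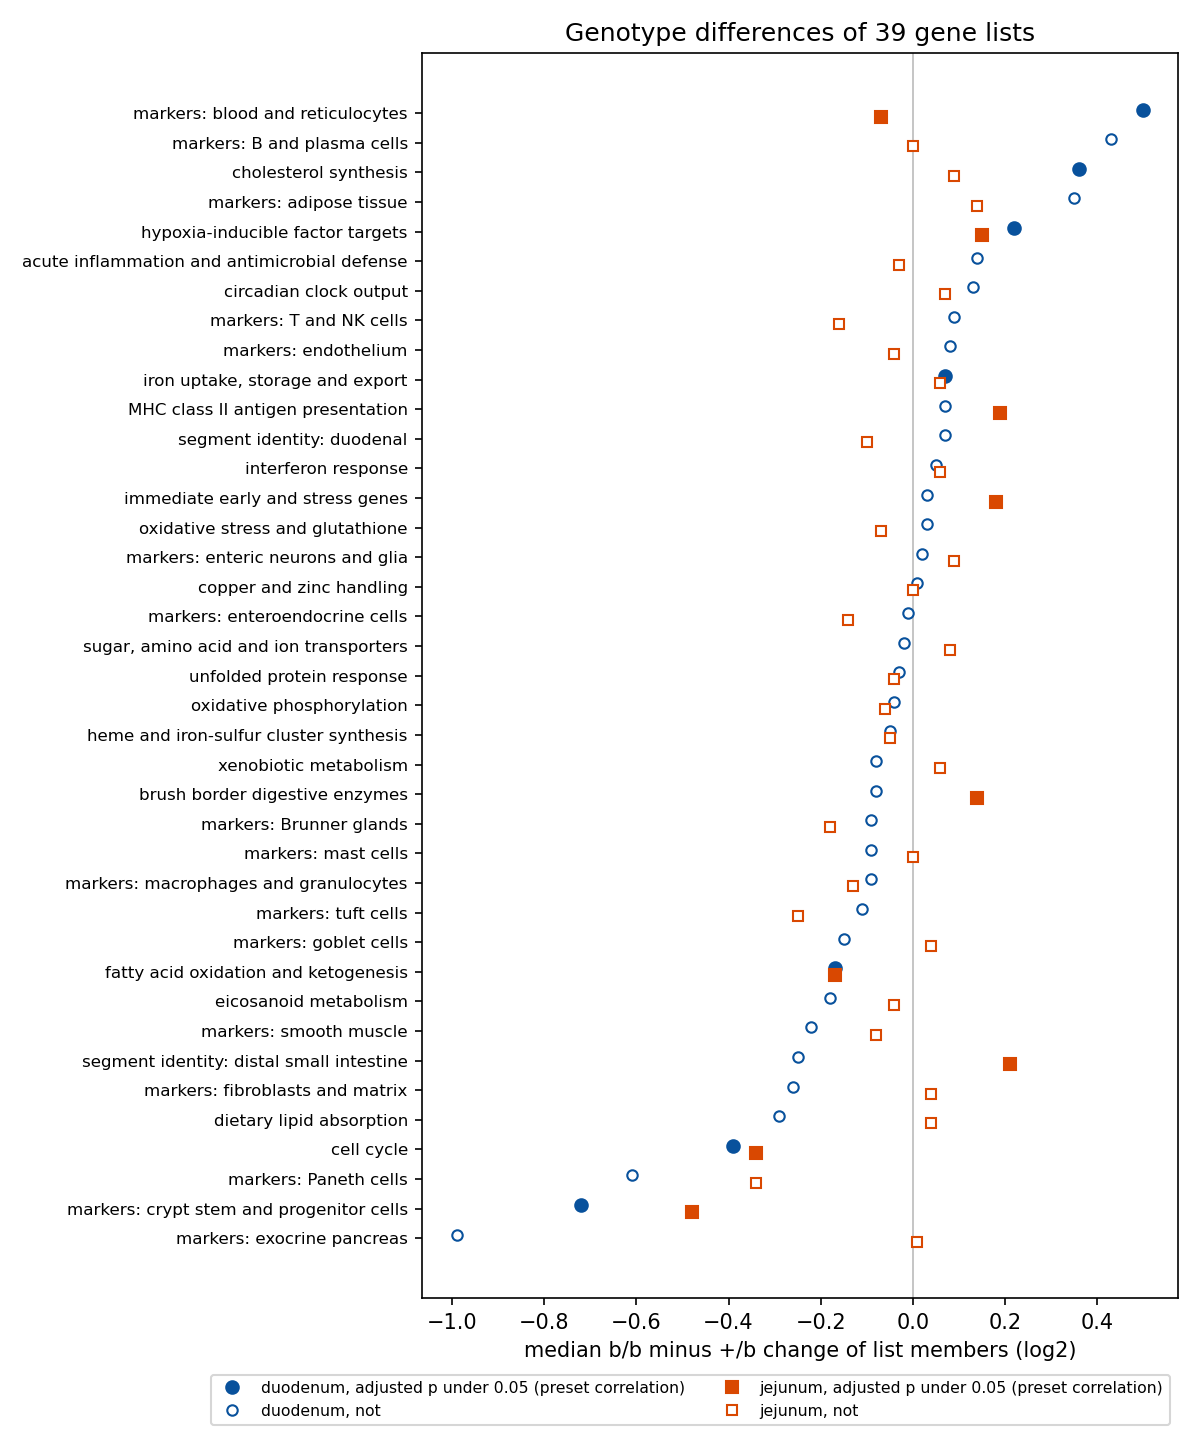
Median b/b minus +/b change (log2) of the members of 39 gene lists, in duodenum (circles) and jejunum (squares), with filled symbols for an adjusted p under 0.05 at the preset correlation. Crypt and cell cycle lists lie left of 0 in both segments, and only the blood list in duodenum kept its call with an estimated correlation.

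In the jejunum, the genes past the threshold were erythroid genes and Alox15. Alox15 rose by 3.46 ± 0.36 in b/b rats, from 45.4 ± 24.3 to 621 ± 70.9 (limma adjusted p = 0.00236, n = 3 per group). Hbb rose by 2.37 ± 0.26, from 2210 ± 527 to 11400 ± 1960 (limma adjusted p = 0.00236). Alas2 rose by 2.63 ± 0.41 (limma adjusted p = 0.047). The other 3 of the 6 called probe sets (3.58 ± 0.49, 2.22 ± 0.28 and 2.38 ± 0.37) were annotated to several genes. All 6 were higher in b/b with no overlap between the groups, which 7.9% of all probe sets showed, and 237 probe sets had an unadjusted p under 0.05, fewer than the 885 expected by chance.

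Iron uptake genes did not pass the threshold in the jejunum. Cybrd1 had a change of 0.24 ± 0.41, Tfrc 0.22 ± 0.25 and Slc11a2 0.98 ± 0.55 on its brighter probe set (0.25 without b/b replicate 3 and 1.71 without b/b replicate 2) and 0.21 ± 0.38 on its dimmer one. Slc40a1 had -0.18 ± 0.46, Heph 0.10 ± 0.19, Hmox1 0.09 ± 0.53, Mt1 0.48 ± 0.81 and Atp7a -0.02 ± 0.46. The count was 2 without b/b replicate 1 or 3 and 3 without replicate 2 of either genotype, and Alox15 and Hbb passed in each of the 6 fits that left out 1 array. Alas2 passed only without +/b replicate 1 (limma adjusted p from 0.122 to 0.494 in the other 5 fits).

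For the jejunum, 9 lists were called at the preset correlation and 0 with an estimated one. Cell cycle genes had a median of -0.34, 38 of 39 below 0 (limma camera adjusted p = 1.02e-06, and adjusted p = 0.761 with an estimated correlation). Crypt markers had -0.48 (limma adjusted p = 0.243 with an estimated correlation) and fatty acid oxidation genes -0.17 (limma adjusted p = 0.764 with an estimated correlation). Hypoxia-inducible factor targets had 0.15 (limma adjusted p = 0.223 with an estimated correlation), MHC class II genes 0.19 (limma adjusted p = 0.761 with an estimated correlation) and brush border enzymes 0.14 (limma adjusted p = 0.84 with an estimated correlation). Immediate early genes had 0.18 (limma adjusted p = 0.243 with an estimated correlation) and distal small intestine genes 0.21 (limma adjusted p = 0.764 with an estimated correlation). The blood list was called higher with a mean of 0.38 but a median of -0.07 (limma adjusted p = 0.223 with an estimated correlation). Its Hbb and Alas2 passed both over all probe sets and when adjusted over the list alone, and of the other 8 lists 0 members passed either way. Without b/b replicate 2 there were 15 calls, the cell cycle call was lost without +/b replicate 3 (-0.17, limma adjusted p = 0.0644), and of the 9 lists only the crypt and hypoxia-inducible factor lists were called in each of the 6 fits. The brush border and MHC class II calls were lost without +/b replicate 3 or b/b replicate 1 (limma adjusted p up to 0.855 and 0.838), with medians of -0.13 without b/b replicate 1 for the first and -0.07 without +/b replicate 3 for the second, and the fatty acid oxidation call without +/b replicate 3 or b/b replicate 2 or 3 (up to 0.803). The immediate early call was lost without +/b replicate 1 or 3 or b/b replicate 2 or 3 (limma adjusted p up to 0.155), the distal call without replicate 2 of either genotype, +/b replicate 3 or b/b replicate 1 (up to 0.672), and the blood call without b/b replicate 3 (0.114).

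The genotype effects of both segments shared 4 called probe sets, or 2 without b/b jejunum replicate 1 or 3, all higher in b/b: Alox15, Hbb and a pair of probe sets annotated to several genes. Independent lists of these sizes would share 0.00237. That figure treats each probe set as separate, although the pair changed much as Hbb did. Both contrasts also take the spread of each probe set from the same fit, so the figure gives no test. The pair had 2.45 and 2.68 in the duodenum and 2.22 and 2.38 in the jejunum, against 2.43 and 2.37 for Hbb. Across all probe sets, which are not independent replicates, the log2 changes of both segments correlated at r = 0.185 (Spearman 0.177). The contrasts share no array, but each pair of tissues came from the same rats.

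The interaction asked whether the genotype effect differed between the segments. Cybrd1 differed most among the genes fixed in advance, with a jejunum minus duodenum difference of -3.80 ± 0.58 (interval on 8 residual degrees of freedom -5.15 to -2.46), and Tfrc had -1.13 ± 0.35 (-1.94 to -0.32). Adjusted over these 9 genes alone they gave limma adjusted p = 0.000128 and 0.0288, but over all probe sets 0.252 and 1. The plan for the interaction adjusted over all probe sets, and the adjustment over the 9 genes was not part of it. Slc11a2 had -1.65 ± 0.78 on its brighter probe set (-3.44 to 0.15, limma adjusted p = 0.125 over the 9 genes). On the dimmer one, not among the 9, it had -2.60 ± 0.54 (limma unadjusted p = 0.000274). The dimmer Tfrc probe set, also not among the 9, had -0.86 ± 0.56 (limma unadjusted p = 0.149). Alox15 had -1.07 ± 0.51 (-2.24 to 0.11). These intervals use the residual degrees of freedom alone, so they are wider than the limma p-values imply. Over all 17694 probe sets limma called 0, with 306 at an unadjusted p under 0.05, and 2 without b/b duodenum replicate 1, Cybrd1 among them (adjusted p = 4.92e-04). With the rat group as a block, which follows the pairing given in the series design, 2 were called. They were Cybrd1 (-3.80 ± 0.40, limma adjusted p = 0.0218) and the probe set with no gene in the annotation that was higher in b/b duodenum (-4.04 ± 0.46, limma adjusted p = 0.0223). Among the 9 genes Slc11a2 on its brighter probe set (adjusted p = 0.0411) and Atp7a (-1.17 ± 0.40, adjusted p = 0.0401 in limma) also passed with that block. At the preset correlation camera called 5 lists, and 0 with an estimated correlation (adjusted p from 0.392 to 0.866 with an estimated correlation).

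Along the intestine of +/b rats, the jejunum had more Plb1, a brush border phospholipase (4.95 ± 0.62 on the log2 scale, n = 3 per segment), Tmigd1 (3.86 ± 0.57) and Cmahp (2.40 ± 0.38) than the duodenum. It had less Akp3, an intestinal alkaline phosphatase (-5.61 ± 0.89), S100g, the vitamin D-dependent calcium-binding protein (-4.03 ± 0.30), Pdx1, a transcription factor of the duodenum and pancreas (-3.48 ± 0.53), and Slc40a1 (-2.73 ± 0.43). Htatip2 (-1.54 ± 0.17) and Ldhd (-1.47 ± 0.22) were also lower. With 1 probe set that has no gene in the annotation (2.16 ± 0.30), these made up the 10 called probe sets, 4 higher and 6 lower, with limma adjusted p between 4.01e-05 for S100g and 0.0371 for Akp3 and Cmahp. There were 948 at an unadjusted p under 0.05, 582 higher and 366 lower. With the rat group as a block 86 were called, 30 higher and 56 lower, including all 10. Median centring gave 6 higher and 2 lower, and without rescaling 8662 of 8673 calls were higher, with a median change of 1.605 over all probe sets. The count was 3 without +/b duodenum replicate 1, 21 without replicate 2, 2 without replicate 3 and 3 without +/b jejunum replicate 1 or 2, and of the 9 genes S100g and Htatip2 passed in each of the 6 such fits. Plb1 lost the call without +/b duodenum replicate 1 or 3 (limma adjusted p up to 0.0601), and Tmigd1, Cmahp and Pdx1 also without +/b jejunum replicate 1 or 2 (up to 0.278). Akp3 and Slc40a1 passed only without +/b jejunum replicate 3, and Ldhd in none of the fits (limma adjusted p up to 0.278).

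In b/b rats the same contrast called 135 probe sets, 61 higher and 74 lower in the jejunum, and 431 (208 higher, 223 lower) with the rat group as a block. The balance was the other way with that block random (188 higher, 163 lower), with array weights (369 and 273) and among the 1728 at an unadjusted p under 0.05 (1108 and 620). Plb1 was again most raised (6.21 ± 0.62), followed by Tmigd1 (5.30 ± 0.57), Osr2 (4.29 ± 0.51), the enteroendocrine peptide Nts (3.94 ± 0.56) and Cmahp (3.86 ± 0.43). Pla2g2a, a secretory phospholipase of Paneth cells (3.79 ± 0.64), the vitamin B12 receptor Cubn (3.70 ± 0.48), Fam151a (3.43 ± 0.58), Folr1 (3.34 ± 0.37) and Gnai1 (3.23 ± 0.63) also rose. The lower genes were Akp3 (-6.13 ± 0.89), Cybrd1 (-5.61 ± 0.41), S100g (-4.61 ± 0.30), Pdx1 (-4.53 ± 0.53), Slc11a2 (-4.25 ± 0.55) and Slc40a1 (-3.41 ± 0.46). They also included the glucuronosyltransferases Ugt2b7 (-3.66 ± 0.58) and Ugt2b35 (-3.16 ± 0.48) and the alcohol dehydrogenases Adh1c (-3.52 ± 0.66) and Adh7 (-3.47 ± 0.62). For these 20 genes limma adjusted p lay between 6.92e-06 for S100g and 0.0302 for Gnai1. The count was 235, 40 and 56 without b/b duodenum replicates 1, 2 and 3 and 87, 33 and 83 without b/b jejunum replicates 1, 2 and 3. Of the 20 genes, Pla2g2a, Fam151a, Gnai1, Ugt2b7, Ugt2b35, Adh1c and Adh7 lost the call in at least 1 of these 6 fits, each of them without b/b jejunum replicate 2 (limma adjusted p up to 0.165).

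All 10 probe sets called in +/b were called in b/b rats in the same direction, against 0.0138 higher and 0.0251 lower expected of independent lists. Both contrasts take the spread of each probe set from the same fit, so these lists are not independent and the expected figures give no test. Of the 135 called in b/b, 134 had the same sign in +/b. Selection in b/b favours larger values there, and the interaction without a block called 0 probe sets (306 at an unadjusted p under 0.05 in limma). With the rat group as a block it called 2 of the 135, Cybrd1 and the probe set with no gene in the annotation named with it. Across all probe sets, which are not independent replicates, the changes correlated at r = 0.448 (Spearman 0.355).

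**Figure D3:**
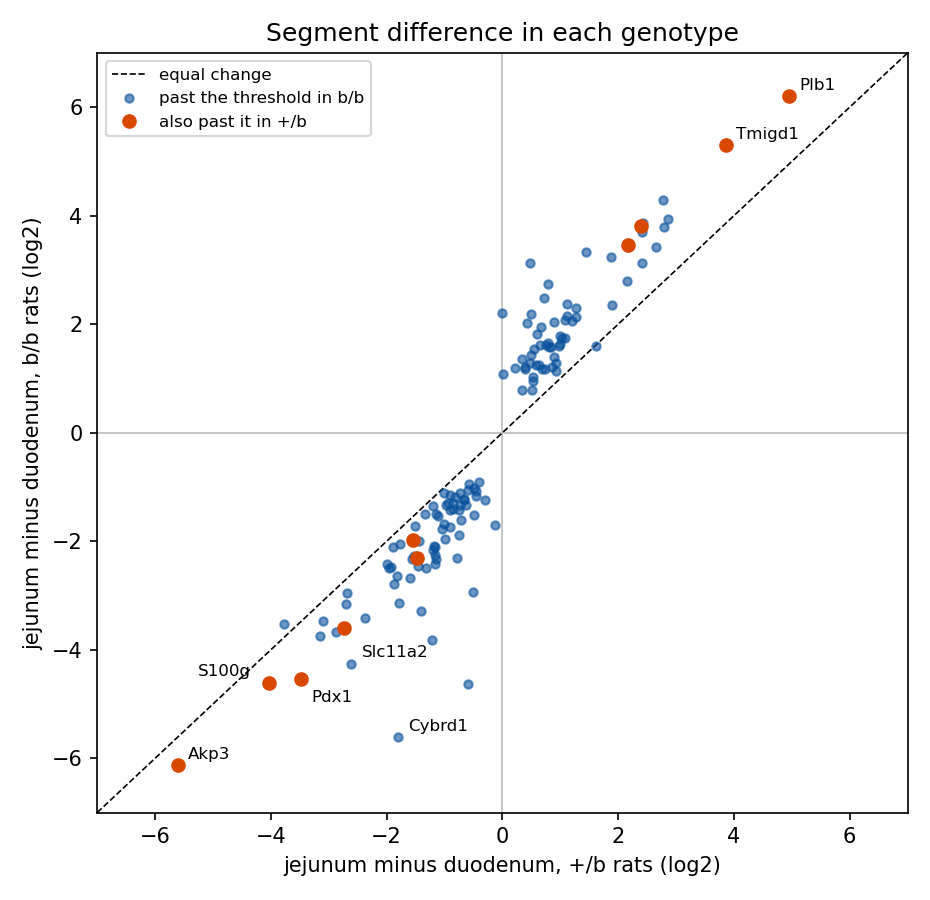
Jejunum minus duodenum change (log2) in +/b rats (x axis) and b/b rats (y axis) of the 135 probe sets past the threshold in b/b rats, with the 10 that also passed in +/b as larger points and equal change as a dashed line. Cybrd1 lies at -1.81 in +/b and -5.61 in b/b rats.

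Of 15 lists called per genotype, 2 in each kept the call with an estimated correlation. The duodenal identity list was lower in the jejunum, with a median of -0.59 in +/b (limma adjusted p = 0.0142 with an estimated correlation) and -1.05 in b/b rats (limma adjusted p = 0.00876 with an estimated correlation). Its genes were chosen as duodenal, so this direction follows from the choice of the list and checks only the segment labels. In +/b rats 2 of its 17 members, S100g and Pdx1, were called over all probe sets and 7 adjusted over the list alone, 6 lower and 1 higher. In b/b rats 6 were called and 10 adjusted over the list alone. Genes of oxidative stress and glutathione had a median of -0.23 in +/b and -0.45 in b/b rats (limma adjusted p = 0.0142 and 0.00876 with an estimated correlation). Their lower members in b/b rats included the peroxidase Gpx4 (-0.90 ± 0.20) and Txnrd1 (-0.77 ± 0.21), with 5 of 36 passing adjusted over the list alone and 0 over all probe sets. In +/b rats 1 member passed adjusted over the list alone, the thioredoxin Txn1 (-0.94 ± 0.21), and 0 over all probe sets.

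The other 13 lists per genotype lost the call with an estimated correlation, with adjusted p from 0.119 to 0.528 in +/b and from 0.0956 to 0.592 in b/b rats in limma. Paneth cell markers, antimicrobial genes of the crypt base, had medians of 1.89 and 2.35, and 4 of 5 passed in each genotype when adjusted over the list alone, among them Mmp7 (3.10 ± 0.59 in +/b) and Defa24 (2.35 ± 0.44 in b/b). Over all probe sets Pla2g2a and Defa24 were called in b/b rats and 0 in +/b. Distal small intestine genes, which were likewise chosen by segment, had medians of 0.36 and 0.71. Of the 15, Nts, Cubn, Gcg (2.80 ± 0.56), Naaladl1 (1.59 ± 0.32) and Pyy (3.13 ± 0.63) were called over all probe sets in b/b rats and 0 in +/b, against 9 (8 higher, 1 lower) and 6 (5 higher, 1 lower) adjusted over the list alone. In +/b rats the list call was lost without jejunum replicate 1 (limma adjusted p = 0.0551). Cholesterol synthesis had -0.54 and -0.63, with 20 of 20 genes below 0 in each. In b/b rats Tm7sf2, a sterol reductase (-1.12 ± 0.20), was called over all probe sets, and adjusted over the list alone 10 passed, against 1 in +/b. Cell cycle genes had 0.57 and 0.63, with 0 called over all probe sets on the brightest probe set of each gene and 0 and 4 adjusted over the list alone, while a dimmer probe set of Top2a was called in b/b rats (1.61, limma adjusted p = 0.0318). Transporters were called lower in b/b rats with a mean of -0.34 but a median of 0.00, a call lost without b/b duodenum replicate 1 or jejunum replicate 2 (limma adjusted p from 0.115 to 0.185). Pancreas markers had -2.36 in +/b rats, 0.13 without +/b duodenum replicate 2, and -1.06 in b/b rats, -0.21 without b/b duodenum replicate 3.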

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

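The test of blood RNA for Slc11a2, Cybrd1 and Tfrc, its repeats beside the blood markers and as added signal, the fits without both arrays deposited unscaled and the rat-group block in the interaction were chosen only after the results were seen.

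A difference of the genotype effect between the segments (jejunum minus duodenum, log2) marked 2 of the 9 genes fixed in advance, adjusted over these genes alone. They were Cybrd1 with -3.80 ± 0.58 and Tfrc, on its brighter probe set, with -1.13 ± 0.35. The difference also marked 5 gene lists, of which 0 kept the call with an estimated correlation. The median difference was 0.56 for distal small intestine genes (limma adjusted p = 0.841 with an estimated correlation), -0.48 for duodenal identity genes (limma adjusted p = 0.664 with an estimated correlation) and -0.52 for blood and reticulocyte markers (limma adjusted p = 0.392 with an estimated correlation). Dietary lipid absorption genes had 0.30 (limma adjusted p = 0.866 with an estimated correlation) and B and plasma cell markers -0.67 (limma adjusted p = 0.841 with an estimated correlation), or -0.07 without both arrays deposited unscaled. Without 1 array at a time the first list was called in 11 of 12 fits, the second and the blood list in 9 and the others in 6, and 2 lists were called without b/b duodenum replicate 2 and 8 without b/b jejunum replicate 2. The duodenal and distal lists hold genes that differ between segments by choice, and Cybrd1 and Slc40a1 belong to the duodenal one. Groups of 3 arrays were not tested for single outlying arrays.

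Slc11a2, Cybrd1 and Tfrc had larger genotype changes in the duodenum than in the jejunum. Among the 9 genes, each on its brightest probe set, this difference passed for Cybrd1 and Tfrc. The dimmer Tfrc probe set had -0.86 ± 0.56 (limma unadjusted p = 0.149), so the Tfrc result rests on the brighter one. For Slc11a2 the difference passed only with the rat group as a block (-1.65 ± 0.60, limma adjusted p = 0.0411, against 0.125 without it). The interval was -3.30 to 0.01 on 4 residual degrees of freedom with the block and -3.44 to 0.15 without it. Both intervals use the residual degrees of freedom alone and are wider than the limma p-values imply. The dimmer Slc11a2 probe set, not among the 9, had -2.60 ± 0.54 without a block (limma unadjusted p = 0.000274). Blood RNA that brings Hbb and Alas2 is argued against for Cybrd1 and Slc11a2, because their highest addition of signal in b/b jejunum was 0.0715 and 0.457 of the lowest expected from the additions of Hbb or Alas2 (for Slc11a2, 3260 against 7130), and because Cybrd1 had -3.31 (interval -5.35 to -1.26) in the interaction relative to the blood list. For Tfrc it stays open, since the spread of the arrays was too wide to decide. Its mean addition in b/b jejunum was 747, below the 3660 expected from Hbb and the 3930 from Alas2. However, its highest addition was 2.65 times the lowest expected. In the interaction Tfrc had -0.63 (-1.80 to 0.54) relative to the list, but -1.24 (-2.45 to -0.03) relative to Hbb and Alas2. On the log2 scale the brighter Slc11a2 probe set alone did not decide (-1.15, -3.64 to 1.34, relative to the list, and -2.12 standard errors by itself, limma unadjusted p = 0.0527). The mean of the 2 Slc11a2 probe sets had -2.13 ± 0.61 (limma unadjusted p = 0.00379) but was not compared with the blood markers. Without both +/b duodenum arrays deposited unscaled, the median duodenal change of the 3 genes was 3.06, with a fit SE of 0.80 for the middle gene. That median lay above the bound of 1 set before that fit, which argues against those arrays as the whole cause. However, 1 +/b array remained, assumed to vary like the other groups, and Tfrc alone had 0.90. A response of the duodenal mucosa to the iron deficiency of b/b rats, which the genotype implies, may also lie behind the pattern and was not tested apart from the genotype.

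Alox15 was higher in b/b rats in both segments. Markers of macrophages and granulocytes, cells that can express it, had medians of -0.09 and -0.13 over 12 genes. Their largest changes were 0.83 in the duodenum and 0.04 in the jejunum, which argues against a general increase of these cells. The change of Alox15 lay at least 8.79 SD of the members above the medians, a distance that rests on a +/b signal near the floor. More of a small part of these cells that expresses Alox15 was not tested. RNA of reticulocytes, which are known to carry a lipoxygenase of this family, stays open, and the larger rise of Alox15 than of Hbb and Alas2 (by 2.13 in the duodenum and 0.96 in the jejunum) decides nothing, since its +/b signal lay near the floor. The jejunum minus duodenum change of Alox15 in b/b rats differed from that of Hbb and Alas2 by 0.14 ± 0.40, as such a source could give, but its deviations over the 6 b/b arrays did not follow theirs (exact one-sided permutation p = 0.5, with 0.0278 the smallest p that 36 arrangements allow). A change in the mucosal cells themselves was not tested and remains possible.

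Cell cycle and crypt cell lists were lower in b/b rats in both segments at the preset correlation only. A single array decided the call in part, since the cell cycle list was called with a negative median in 10 of 12 fits without 1 array, and lost without +/b duodenum replicate 1 (-0.18) or +/b jejunum replicate 3 (-0.17). Scrapes that took less of the deep mucosa, which would lower the smooth muscle, fibroblast and Paneth cell lists in both segments, stay open and cannot be told apart from fewer dividing cells. The medians of these lists were -0.22, -0.26 and -0.61 in the duodenum but -0.08, 0.04 and -0.34 in the jejunum. Pooled over 42 genes the medians were -0.26 ± 0.09 and -0.10 ± 0.06. Here ± is an error over genes, which share arrays, and leaves out the spread between groups of rats. Of the 10 splits of the 6 duodenum arrays, 6 gave at least as many called lists as the real 7 (up to 13), and of the 10 splits of the jejunum arrays 7 gave at least the real 9 (up to 14), splits too few for a share under 0.05.

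Splits of the arrays were also counted for the other results. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split alone gave as many called probe sets (1 of 10) in each contrast, with 7 for genotype in duodenum, 6 for genotype in jejunum, 10 for segment in +/b and 135 for segment in b/b rats, and 0 as the highest of the other splits. Called lists numbered 15 in each segment contrast, reached by 1 of 10 splits, against up to 12 in +/b and 14 in b/b rats in the others. Where the numbers pair the arrays, the 3 other splits that parted all pairs called 0 probe sets and up to 14, 10 and 12 lists in the jejunum, +/b and b/b contrasts. For the interaction the real count was 0 (306 at an unadjusted p under 0.05 in limma), which any split must reach (100 of 100), so those splits tested nothing. At least the real 5 lists were called in 85 of 100 splits (up to 16), so for the lists chance was not excluded. A split that put +/b duodenum replicates 1 and 2 with b/b duodenum replicate 1, and +/b jejunum replicate 3 with b/b jejunum replicates 2 and 3, called 233 probe sets. In each segment this split kept the arrays numbered 1 together and those numbered 3 together, with 1 array numbered 2 on each side. Its contrast thus set number 1 against number 3, which points to a difference between the replicate numbers. The main fits held no term for the replicate number.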

How the results depend on the processing

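The fits without both arrays deposited unscaled, with the replicate number as a block in the segment contrasts and with the rat group as a block in the interaction were chosen only after the data were seen. Of the values of named genes and lists under the alternatives, 1460 kept their direction and side of the threshold, 297 lost the call, 13 gained it and 21 turned sign. Of the counts, 118 stayed within 1.5 times and 68 did not. Where no cause is named, the cause was not tested.

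Without rescaling, genotype in duodenum gave 366 probe sets (median of all 1.513) and segment in +/b 8673 (median of all 1.605), because 2 arrays then stood lower as a whole, and genotype in jejunum gave 2, segment in b/b 40 and the interaction 2 (median of all -1.551). In +/b Htatip2 then had 0.19 and Ldhd 0.24, below that median. A pseudocount of 1 gave 3 for genotype in jejunum and 6 for segment in +/b. No filter gave 17 for segment in +/b and 11 lists for genotype in duodenum. Median centring gave 64 for segment in b/b, and quantile normalization 8 lists for the interaction. Without an intensity trend there were 2 for genotype in jejunum, 2 for segment in +/b and 63 for segment in b/b, and Slc11a2 in duodenum lost its call (adjusted p = 0.0759, against 0.0576 with median centring, in limma). Array weights gave 18 for segment in +/b, 642 for segment in b/b and 2 for the interaction, with Mt1 at -0.40 in duodenum and -0.05 in jejunum. Fitting only the arrays of the contrast gave 16 and 82 for segment in +/b and b/b. The mean of all probe sets of a gene gave 2 lists for the interaction.

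An estimated correlation left 1 list for genotype in duodenum, 0 in jejunum, 2 for segment in +/b, 2 in b/b and 0 for the interaction, and fry gave 1, 0, 3, 4 and 0. Without both arrays deposited unscaled, genotype in duodenum gave 3 (2 of the 7 kept), segment in +/b 5 (1 of the 10 kept), Mt1 -0.28 in duodenum and the B and plasma cell list -0.07 in the interaction, with 1 +/b duodenum array left that is assumed to vary like the other groups.

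As blocks, the rat group gave 86 for segment in +/b, 431 in b/b and 2 for the interaction, and as a random block 55, 351 and 2. With the rat group as a fixed block 19 lists were called for segment in +/b (15 kept) and 15 in b/b (14 kept), the crypt cell list being the call lost (limma adjusted p = 0.0775). The replicate number as a block gave 15 for genotype in duodenum with 11 lists, 71 and 398 for segment in +/b and b/b, 3 for the interaction and 7 probe sets shared by both genotype contrasts. The pairing of duodenum arrays across genotypes was not borne out (correlations from -0.06 to 0.16, not each highest with its own number). The 15 included Tfrc (1.35, limma adjusted p = 0.026), Alas1 (0.99) and Hacd3 (-1.36). With the blocks every called probe set stayed called, and in the interaction Cybrd1 was called with each block (limma adjusted p between 0.0207 and 0.0464) and Slc11a2 on its dimmer probe set with the number block (0.0464).

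Without 1 array at a time, fits in which an arm of 2 arrays remained gave 5 to 8 probe sets for genotype in duodenum, 2 to 6 in jejunum, 2 to 21 for segment in +/b, 33 to 235 in b/b and 0 to 2 for the interaction, 2 to 5 shared by both genotype contrasts, and 4 to 12, 7 to 15, 12 to 16, 13 to 16 and 2 to 8 lists. None of the uncalled genes that turned sign was near the threshold. In duodenum Mt1 ranged from -0.47 to 0.89 (-0.16 without +/b replicate 3) and Heph from -0.03 to 0.13. In jejunum Mt1 ranged from -0.44 to 1.17, Hmox1 from -0.28 to 0.43 (-0.17 without b/b replicate 3), Slc40a1 from -0.65 to 0.11 (0.03 and 0.08 in others), Atp7a from -0.29 to 0.15 (0.04, 0.14 and 0.07 in others), Slc11a2 on its dimmer probe set from -0.13 to 0.53 and the brush border list from -0.13 to 0.36. The medians of the cholesterol synthesis list in duodenum (-0.02 to 0.76) and of the MHC class II list in jejunum (-0.07 to 0.48) also turned sign, though the direction of their camera test did not. Dim probe sets limit these values: between 34.4% and 48.0% of probe sets lay under a signal of 100 on each array, and on the rescaled arrays their noise was multiplied too.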

Other observations

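The genes and lists named here were chosen after their values were seen, except that the lists were fixed in advance.

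Hormone genes of enteroendocrine cells split by segment. In b/b rats the jejunum had more Nts (3.94 ± 0.56 on the log2 scale, n = 3 per segment), Pyy (3.13 ± 0.63) and Gcg (2.80 ± 0.56), and less Ghrl, the ghrelin gene (-2.27 ± 0.48), and Sct, the secretin gene (-1.05 ± 0.20), than the duodenum, with limma adjusted p between 0.00474 and 0.0415. The list of 13 genes as a whole was not called (median -0.26, mean 0.30, limma camera adjusted p = 0.36), since its members went both ways. In +/b rats the same 5 genes had the same signs, 2.86 ± 0.56, 2.41 ± 0.63, 2.15 ± 0.56, -1.53 ± 0.48 and -0.59 ± 0.20, and passed when adjusted over the list alone, as did Sst (-0.66 ± 0.24), but not over all probe sets.

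Iron genes also went both ways along the intestine of b/b rats. Cybrd1, Slc11a2 and Slc40a1 were lower in the jejunum, while Slc39a8, a metal ion transporter, was higher (1.02 ± 0.18, limma adjusted p = 0.018), and the list of 24 genes was not called (median 0.04, mean -0.62, limma adjusted p = 0.106). Car9, a carbonic anhydrase induced by hypoxia, was 4-fold lower in the jejunum than in the duodenum of b/b rats (limma adjusted p = 0.00112) and had -1.44 ± 0.25 in +/b rats, where it passed adjusted over its list alone. With the rat group as a block, the +/b contrast also called Adh1c (-3.77 ± 0.35), Ugt2b7 (-2.88 ± 0.28), Slc11a2 (-2.61 ± 0.42), Cybrd1 (-1.81 ± 0.29), Cubn (2.41 ± 0.25) and Pla2g2a (2.79 ± 0.35), with limma adjusted p between 0.00201 and 0.0208.

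A probe set with no gene in the annotation followed the pattern of Cybrd1. Its signal was 513 ± 111 in +/b duodenum, 9350 ± 5650 in b/b duodenum, 336 in +/b jejunum and 316 in b/b jejunum, against 843, 16000, 224 and 267 for Cybrd1.

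Exocrine pancreas markers varied between single arrays. The mean log2 level of 18 genes was 13.56 in +/b duodenum replicate 2, 1 of the 2 arrays deposited unscaled, and 9.56 in b/b duodenum replicate 3, and lay between 6.50 and 7.34 in the other 10 arrays. Spike-in transcripts added to each hybridisation varied with the replicate number. The scaled signal of the CreX control was 51400 to 96300 on the 4 arrays numbered 1, 30300 to 48700 on those numbered 2 and 15400 to 32000 on those numbered 3. The BioB control gave 3030 to 6140, 1280 to 2250 and 351 to 1240.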
